A study of Mus musculus with 18 samples.

How the data were processed

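Total RNA was extracted with Trizol, labelled as biotinylated cRNA and hybridised to Affymetrix mouse genome arrays, per the labels' protocols. The values used are the probe set intensities that the authors deposited as 1 table for all 18 arrays, on a linear scale. How probe intensities were summarised and scaled between arrays is not given in the sources used here. The table itself shows 2 forms of values, 1 for the 14 liver arrays and 1 for the 4 arrays of the rest of the embryo, which differ in negative values, exact zeros, upper percentiles and control transcripts. These 2 sets of arrays were therefore processed or scaled in different ways, and the comparison between tissues crosses them.

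Groups were taken from the source names of the samples, which give tissue and stage. The age entry of the liver samples from 11.5 dpc onward repeats 10.5 dpc, and the titles of the rest-of-embryo samples name liver, so neither was used. The treatment text of the adult samples describes a liver resection, while their title, source and description give baseline normal liver, and they were taken as normal adult liver. Nothing beyond the word biological says whether replicate arrays came from separate litters, so p-values measure the spread between these samples. The replicate numbers of the labels name the arrays and were not used to pair them.

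The table held 45101 probe sets, of which 64 were controls. A single gene symbol was given for 34945, several for 932 and none for 9160 in the array annotation used here. Symbols were updated through gene identifiers where the reference table held them, and only probe sets with 1 symbol were named, giving 18193 genes. Each gene was represented by its probe set with the highest mean log2 value over all 18 arrays. Intensities were raised to a floor of 24.8, the 20th percentile of all values, and then taken to log2. A gene was tested in a fit when its probe set exceeded 77.9, the 50th percentile of all values, on at least 2 arrays of that fit. This left 14127 genes in the liver fit, 14896 in the tissue fits and 15544 in the fit of all arrays. Array medians differed by 0.62 log2, and no further normalization between arrays was applied in the results as reported. Of the probe sets, 5071 read below 0 on at least 1 liver array, and changes of such genes are compressed by the floor. Where all arrays of 1 group lay at or under the floor, the fold difference is a lower bound and is given as at least that value. Where only some arrays of the lower group did, the floor also shrinks the difference, which is given in log2, and these genes are named where most of the arrays of that group, or 1 of 2, lay there. Arrays at the floor share 1 value and add no spread to the fit. The SE and adjusted p of such genes are therefore too small. The signal over background and the number of arrays limit the precision.

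Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over all genes of a comparison. The 14 liver arrays entered 1 fit with a mean per group and 7 residual degrees of freedom, which gave the contrasts of 16.5 against 10.5 dpc, of successive stages, of any stage by a moderated F test, and of adult against embryonic liver. The tissues were compared over 12 arrays at the 4 matched stages, with stage as a factor. The change of the tissue difference with stage was the interaction of tissue with days post conception, in log2 per day. Single-stage tissue differences came from a fit of all 18 arrays. A gene was called at an adjusted p under 0.05 and a difference of at least 1 log2, or 0.25 log2 per day for a slope. Each call was also counted with the adjustment over the list alone for members of a gene list. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 48 lists of a comparison, and again with the correlation estimated from the residuals.

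The groups, tests, 48 gene lists, thresholds and most alternatives were fixed before the data were examined. So was the rule for the genes named. For each of the 3 main comparisons it takes the 3 called genes with the largest increase and the 3 with the largest decrease among those whose groups of arrays do not overlap, passing over predicted genes. For the tissue comparison, both liver arrays had to lie on the same side of the other array at every stage. From each list assigned to a comparison it takes up to 2 called members with the largest absolute difference, or the member with the smallest adjusted p where none was called. For the slope it takes the 3 called genes with the largest difference in each direction. Albumin, alpha-fetoprotein and sex-linked genes were read on every array to check the labels. Genes outside the rule are named as such.

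The test code was tested on simulated data with 200 changed genes. For 16.5 against 10.5 dpc, 22% of genes changed by 1 log2 and 90% of those changed by 2 log2 were called, with 3 unchanged genes called among 14127. For adult against embryonic liver the shares were 54% and 94%. For the tissue difference they were 40% and 96% among 14896 genes. For the slope, 6% of genes changed by 0.25 log2 per day and 58% of those changed by 0.5 log2 per day were called. The smallest sizes equal the calling limits, so estimates that fall short of them are not called at any precision. For 16.5 against 10.5 dpc, 64% of the genes changed by 1 log2 passed the adjusted p. Simulated noise was normal and independent between genes, and simulated values were not floored, so these shares and false calls need not hold for the data.

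Alternatives covered quantile normalization, median centring, other filters and floors, a variance model without trend, the mean over probe sets, probe sets without the _x_at and _s_at names, 1 fit of all arrays, the replicate number as a block, other thresholds, other contrasts and leaving out each array in turn. Scaling to the hybridisation controls, leaving out probe sets below 0 on any liver array, and leaving out the 10.5 and 12.5 dpc arrays were added after seeing the data.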

Results

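Transcript levels were measured on 18 Affymetrix mouse genome arrays hybridised with RNA of CD-1 mice, an outbred laboratory strain. Embryonic liver was sampled daily from 10.5 to 14.5 days post conception (dpc) and again at 16.5 dpc, 6 stages with 2 arrays each. Liver of 10-week-old females was measured on 2 arrays. The embryo without its liver, called the rest of the embryo here, was measured with 1 array per stage at 4 of these stages, the first 3 and 14.5 dpc. Each embryonic sample was a pool of at least 5 embryos, and the labels call the arrays of a group biological replicates without further detail on how independent the pools were. The number of arrays limits the precision of every value below. Replicate arrays of liver correlated across probe sets with Pearson r between 0.948 at 10.5 dpc and 0.980 at 14.5 dpc, and the adult pair with r = 0.961. The highest correlation between an embryonic liver array and a rest-of-embryo array was 0.774.

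The 14 liver arrays and the 4 rest-of-embryo arrays differed in the form of their values. Median intensity was at most 79.4 on the liver arrays and 91.9 to 107 on the others. Each liver array held 1216 to 1535 values below 0 and no value of exactly 0, whereas the rest-of-embryo arrays held 35 to 41 values of exactly 0 and none below 0. The 99th percentile of intensity was 1319 to 2881 on the liver arrays and 5490 to 5912 on the others.

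Albumin (Alb), the main plasma protein made by hepatocytes, read 956 and 1541 on the liver arrays of 10.5 dpc and 8651 and 8695 on those of 16.5 dpc. In the rest of the embryo it read 122, 105, 303 and 1220 from 10.5 to 14.5 dpc. Alpha-fetoprotein (Afp), the fetal serum protein related to albumin, read between 4525 and 6574 on the 12 embryonic liver arrays and 13.4 and 7.60 on the adult arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty read between -1.74 and 24.9 on the 2 adult arrays, whose animals the labels give as female. The 3' to 5' intensity ratio of Gapdh, a measure of RNA integrity, was 2.82 on replicate 1 of 10.5 dpc and 0.744 to 0.886 on the 11.5 to 16.5 dpc liver arrays.

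The first comparison asked which genes changed over the course of embryonic liver development, from 10.5 to 16.5 dpc. The genes that rose included most of the plasma protein list. Of 22 tested plasma protein genes 19 rose, none fell and 3 were not called, with a median change of 2.58 log2. Fetuin A (Ahsg), a serum glycoprotein, rose at least 136-fold, from 4.59 ± 1.76 to 3375 ± 32.2 intensity units (SD, n = 2 each; 7.09 log2, SE 0.19, limma adjusted p = 1.2e-08). Apolipoprotein H (Apoh) rose at least 114-fold, to 2843 ± 117 (6.84 log2, SE 0.26, adjusted p = 6.15e-08). Of 18 genes of the urea cycle and amino acid breakdown 12 rose and 1 fell, with 5 not called. Ornithine transcarbamylase (Otc), a urea cycle enzyme, rose by 4.17 log2 (SE 0.32, adjusted p = 3.67e-06). Urocanate hydratase (Uroc1), an enzyme of histidine breakdown, rose by 3.14 log2 (SE 0.19), at least 8.79-fold, but its other tested probe set read -0.85 log2 and their mean, 1.14 log2, was not called. The falling member was Got1, a cytosolic aminotransferase, at -1.11 log2, named after its value was seen. Of 22 cytochrome P450 genes 7 rose and none fell, among them Cyp2d26 at 3.07 log2, at least 8.42-fold, and Cyp2d10 at 2.66 log2, at least 6.34-fold. Counts adjusted over the list alone were the same for these 3 lists. The camera set test called the plasma protein list (adjusted p = 7.13e-12, but adjusted p = 0.108 with an estimated correlation) and the urea cycle list (adjusted p = 0.000479, but adjusted p = 0.122 with an estimated correlation). It did not call the P450 list (adjusted p = 0.0982).

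Blood cell genes changed over the same interval. Of 18 genes of definitive red cells 16 rose and 2 were not called, with a median of 3.33 log2. Trim10, a gene of terminal erythroid maturation, rose 31.3-fold from 73.1 ± 0.974 to 2293 ± 64.6 (SD, n = 2 each; 4.97 log2, SE 0.18, adjusted p = 5.96e-08). The adult beta globin Hbb-b2 rose to 2960 ± 142 (6.44 log2, SE 0.35, adjusted p = 4.56e-07) from readings of 47.0 and 11.2, the lower under the floor. Its other tested probe set, however, read -1.83 log2. Of the 3 tested globins of primitive red cells 2 fell, Hbb-bh1 at -3.42 log2 (SE 0.37, adjusted p = 3.94e-05) and Hba-x at -2.20 log2 (SE 0.25, adjusted p = 5.58e-05). Of 23 macrophage and Kupffer cell genes 16 rose and none fell, with a median of 1.58 log2. Cd5l, a protein secreted by tissue macrophages, rose by 5.44 log2, at least 43.4-fold, and lysozyme 1 (Lyz1) by 3.39 log2. Of 16 granule genes of neutrophils and mast cells 12 rose and 1 fell. The calprotectin subunits S100a9 and S100a8 rose by 6.43 log2 (SE 0.14, adjusted p = 3.46e-09) and 6.21 log2 (SE 0.17, adjusted p = 1.51e-08, at least 74.3-fold). The mast cell protease Cpa3 fell by 1.19 log2, named after its value was seen. Of 14 megakaryocyte and platelet genes 3 rose, Ppbp by 2.76 log2, Selp by 1.78 log2 and Gp9 by 1.11 log2, the last named after its value was seen.

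Adjusted over the list alone, 13 granule genes rose and 1 fell, and the counts of the other 4 blood lists were the same. Camera called the red cell list (adjusted p = 2.13e-15, but adjusted p = 0.093 with an estimated correlation) and the macrophage list (adjusted p = 6.59e-10, but adjusted p = 0.096 with an estimated correlation). The primitive globin list had adjusted p = 0.00783, but adjusted p = 0.139 with an estimated correlation. The platelet list also had adjusted p = 0.00783, but adjusted p = 0.108 with an estimated correlation. The granule list was called both ways (adjusted p = 3.41e-08, and adjusted p = 0.0199 with an estimated correlation). Set against 11.5 dpc, with the 10.5 and 12.5 dpc arrays left out, 5 macrophage genes rose and none fell. In that fit 3 platelet genes fell and none rose, with Ppbp at -0.45 log2 and Selp no longer called at 0.93 log2. With the floor at the 40th percentile Selp was not called either, at 0.66 log2. Without replicate 2 of 10.5 dpc, the platelet count, higher minus lower, was 5.

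The genes that fell from 10.5 to 16.5 dpc included members of mesenchymal, TGF-beta, BMP and Wnt lists. Of 17 genes of stellate and mesenchymal cells 11 fell, 1 rose and 5 were not called, with a median of -1.48 log2. The receptor Pdgfra fell by 3.10 log2 (SE 0.16, adjusted p = 4.11e-07) from 883 ± 96.8 to 103 ± 8.78 (SD, n = 2 each). Hand2, a transcription factor of mesenchyme and heart, fell by 2.98 log2 (SE 0.17), with 1 of 2 other tested probe sets at 0.38 log2 and a mean over probe sets of -0.96 log2 that was not called. The rising member was reelin (Reln), at 1.24 log2, named after its value was seen. Of 31 genes of the TGF-beta and BMP pathway 14 fell and 1 rose, the latter Tgfb1 at 1.34 log2, named after its value was seen. Id3, a target of BMP signalling, fell by 2.81 log2 (SE 0.26, adjusted p = 1.31e-05), and the ligand Bmp4 fell by 2.49 log2 (SE 0.28, adjusted p = 5.72e-05). Of 32 Wnt pathway genes 11 fell and none rose. The secreted Wnt modulator Sfrp2 fell by 2.77 log2 and the ligand Wnt2 by 2.70 log2. Of 12 hepatoblast and oncofetal genes 3 fell and 9 were not called. The chromatin protein gene Hmga2 fell 13.5-fold, from 4487 ± 134 to 332 ± 4.41 (-3.75 log2, SE 0.15, adjusted p = 8.54e-08). The imprinted genes Mest and Peg3 fell by 1.91 and 1.44 log2, Peg3 named after its value was seen. Of 26 mitosis genes 6 rose and none fell, among them the proliferation marker Mki67 at 1.87 log2 (SE 0.15) and Ube2c at 1.51 log2 (SE 0.17).

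Adjusted over the list alone, 12 Wnt pathway genes fell, and the counts of the other 4 lists were the same. Camera gave adjusted p = 6.57e-05 for the stellate list (adjusted p = 0.096 with an estimated correlation) and 5.41e-07 for the TGF-beta and BMP list (adjusted p = 0.108 with an estimated correlation). For the Wnt list it gave 0.00022 (adjusted p = 0.093 with an estimated correlation). For the oncofetal list it gave 0.0223 (adjusted p = 0.123 with an estimated correlation), and for the mitosis list 3.94e-05 (adjusted p = 0.106 with an estimated correlation). Transcripts of other tissues fell along with these groups, those of heart muscle in the highest share. Of 16 heart genes 14 fell, with a median of -3.43 log2, and adjusted over the list alone the count was also 14 (camera adjusted p = 2.73e-09, but adjusted p = 0.133 with an estimated correlation). The atrial myosin light chain Myl7 fell from 3469 ± 1039 to 42.6 ± 8.86 (-6.33 log2, SE 0.75, adjusted p = 7.25e-05). The cardiac myosin heavy chain Myh7 fell at least 66.7-fold and the natriuretic peptide Nppa at least 49.8-fold. With the 10.5 and 12.5 dpc arrays left out, 6 stellate, 5 TGF-beta and BMP, 4 Wnt and 1 oncofetal gene fell from 11.5 to 16.5 dpc, with Mest no longer called at -0.98 log2.

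Other tissue lists fell in smaller shares, with members named after their values were seen. Of 16 neural genes 4 fell, Nnat at -3.45 and Tubb3 at -1.24 log2, Nefm at least 10.7-fold and Sox2 at least 3.34-fold, and Syt1 rose by 1.26 log2. Of 17 Hox genes 5 fell, Hoxb2 at -2.63, Hoxb4 at -1.80, Hoxc9 at -1.65 and Hoxa3 at -1.21 log2, and Hoxb6 at least 4.78-fold. Of 13 gut and pancreas genes 3 fell, Barx1 at -2.75 log2, Gcg at least 11.9-fold and Cldn6 at least 8.28-fold. Of 9 lung and kidney genes 3 fell, Wt1 at -2.64 and Foxf1 at -1.51 log2 and Ret at least 3.41-fold. Of 15 cartilage and bone genes 4 fell, Twist1 and Hapln1 each at least 8.18-fold, Sox9 at least 3.60-fold and Col11a1 at -1.36 log2, and 3 rose, Sox6 at 1.75, Ibsp at 1.28 and Comp at 1.07 log2. Of 11 skeletal muscle genes 3 fell, Tnni1 at -3.07, Actc1 at -2.82 and Des at -2.15 log2, and Mylpf rose by 2.94 log2. These counts were the same when adjusted over the list alone. Camera called the Hox list (adjusted p = 0.0287, but adjusted p = 0.139 with an estimated correlation) and none of the other 5, with adjusted p from 0.144 to 0.310. For Otc, S100a9, Selp, Bmp4 and Hoxc9, 1 of the 2 arrays of the lower stage lay at the floor. Set against 11.5 dpc, with the 10.5 and 12.5 dpc arrays left out, 1 heart, 1 neural, 2 Hox, 2 gut and pancreas, 1 lung and kidney and 0 cartilage or skeletal muscle genes fell, while 2 heart, 1 Hox, 1 lung and kidney, 2 cartilage and 4 skeletal muscle genes rose.

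In all, 1471 genes were higher and 986 lower at 16.5 than at 10.5 dpc, 17.4% of the 14127 tested, by limma with an adjusted p under 0.05 and a change of at least 1 log2. Set against 11.5 dpc, with the 10.5 and 12.5 dpc arrays left out, 913 genes were higher and 308 lower. Of the 48 gene lists, camera called 17 higher and 12 lower, and 1 held with an estimated correlation.

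**Figure D1:**
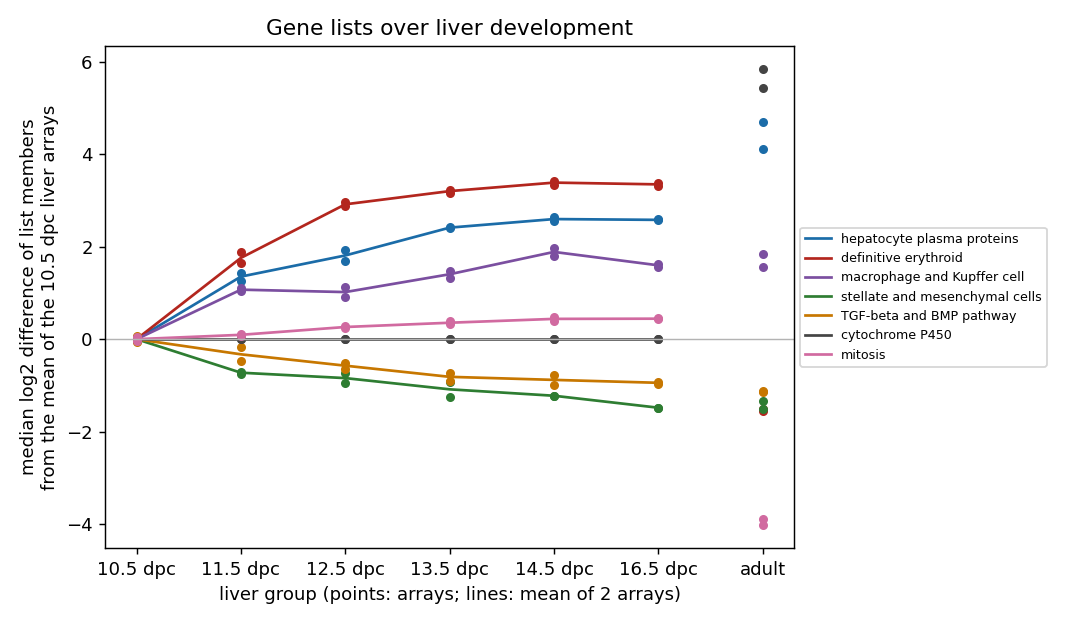
Median log2 difference of the tested members of 7 gene lists from the mean of the 10.5 dpc liver arrays (vertical axis), over the 6 embryonic liver stages and adult liver (horizontal axis). Points are single arrays and lines join the means of 2 arrays. The plasma protein and red cell lists, with median changes of 2.58 and 3.33 log2 from 10.5 to 16.5 dpc, lie above 0 at 16.5 dpc, and the stellate list, at -1.48 log2, lies below it.

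Successive stages were compared to place the changes in time. Between 10.5 and 11.5 dpc 419 genes rose and 380 fell, and between 11.5 and 12.5 dpc 378 rose and 39 fell. After 12.5 dpc the calls numbered 12, 8 and 5 for the 3 remaining steps, with 926, 684 and 882 genes at an unadjusted p under 0.05. Changes under 1 log2 in a step are not counted. In these steps the median change was 0.49, 0.24 and 0.01 log2 for the plasma protein list. It was 0.22, 0.07 and 0.06 log2 for the red cell list and -0.23, -0.11 and -0.18 log2 for the stellate list. Between 13.5 and 16.5 dpc 6 genes were called higher and 10 lower. From 12.5 to 13.5 dpc 3 genes rose, the inter-alpha-trypsin inhibitor heavy chain Itih4 by 2.35 log2, Haao by 1.16 log2 and Sowaha by 1.03 log2, all named after their values were seen. The 9 that fell in that step included the heart list members Myh7, at least 21.6-fold, Nppa, at least 17.4-fold, and Tnnt2 at -3.89 log2, each with adjusted p = 0.0460. From 13.5 to 14.5 dpc 6 genes rose. They included the P450 gene Cyp3a11 at 1.85 log2 (adjusted p = 0.0236) and Akr1d1, a reductase of bile acid synthesis, at 1.60 log2 (adjusted p = 0.00808), both chosen after their values were seen. In the same step Tmem14c fell by 1.58 log2 and Golt1a at least 13.1-fold. From 14.5 to 16.5 dpc Golt1a rose by at least 3.46 log2, while Actg2 and BC048679 fell by 2.41 and 2.21 log2, Cym at least 9.23-fold and Cldn7 at least 2.51-fold, again named after their values were seen. For Itih4 and Akr1d1, 1 of the 2 arrays of the earlier stage lay at the floor. Over all 6 stages, the moderated F test called 2772 genes, and 1278 with the 10.5 and 12.5 dpc arrays left out.

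The heart list moved between single stages. From 10.5 to 11.5 dpc 14 of its 16 genes fell, from 11.5 to 12.5 dpc 8 rose, and from 12.5 to 13.5 dpc 3 fell. The skeletal muscle list moved the same way in the first 2 steps, with 7 of 11 genes lower (median -1.25 log2) and then 6 of 11 higher (median 1.63 log2). Between the 2 arrays of 12.5 dpc its median differed by 0.33 log2, replicate 2 minus replicate 1, and that of the heart list by 1.66 log2. The median intensity of the heart list was 900 and 472 on the arrays of 10.5 dpc, 49.4 and 44.6 at 11.5 dpc, 126 and 355 at 12.5 dpc, and 55.3 and 57.3 at 13.5 dpc. The labels say that tissue around the liver, such as the vena cava behind it, was dissected away. The count for the first step depended on one array: without replicate 2 of 10.5 dpc it was 1723, against 799. The 12 calls from 12.5 to 13.5 dpc did not hold. None was left without any 1 of the 8 arrays of 11.5, 13.5, 14.5 or 16.5 dpc, 1 without either array of 10.5 dpc and 2 without either adult array, while 52 were called without replicate 1 of 12.5 dpc. With the replicate block, with median centring or with all 18 arrays in one fit, 0 genes were called in that step. The 8 calls from 13.5 to 14.5 dpc became 1 without either array of 13.5 dpc, 2 without replicate 1 of 14.5 dpc and 4 without its replicate 2. The 5 calls from 14.5 to 16.5 dpc became 3 without replicate 1 of 14.5 dpc and 8 without replicate 1 of 16.5 dpc.

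**Figure D2:**
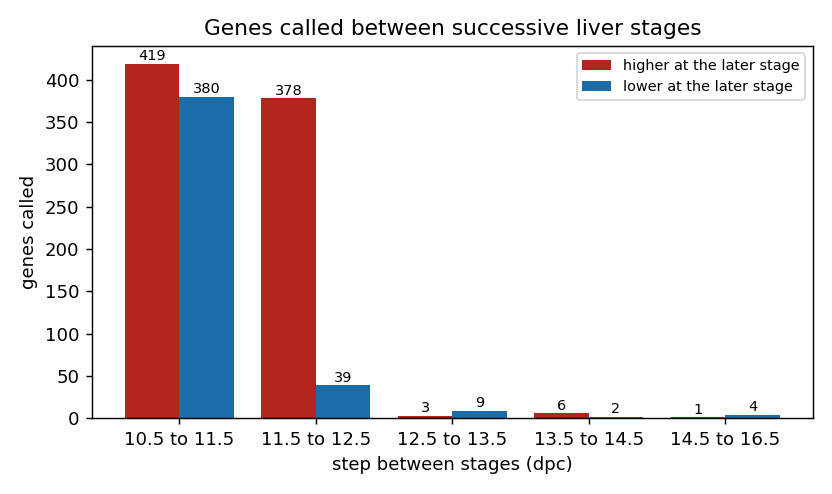
Number of genes called (vertical axis) for each step between successive embryonic liver stages (horizontal axis, dpc), with genes higher and lower at the later stage as separate bars. The first step gave 419 and 380 genes and the second 378 and 39, and each later step at most 12.

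**Figure D3:**
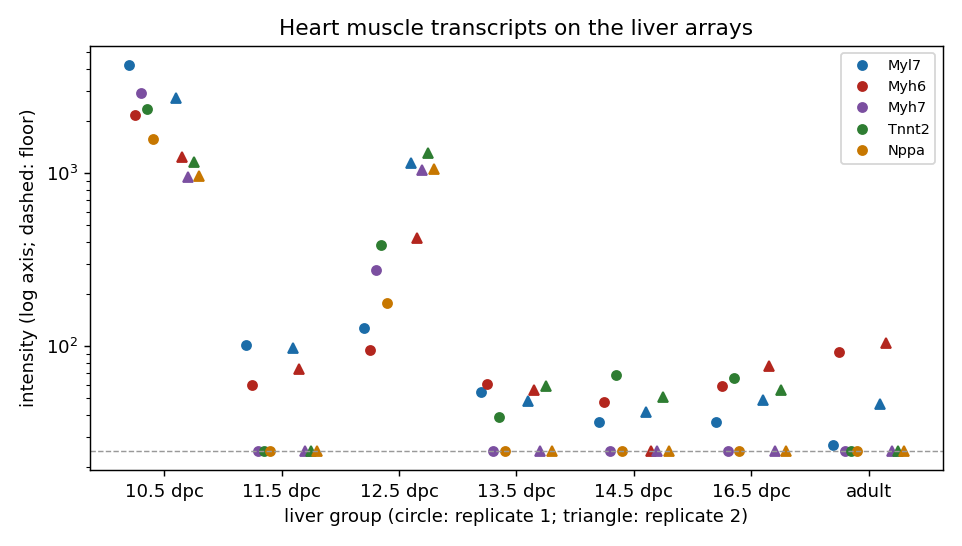
Intensity (log axis, values at or under the floor drawn at the dashed floor line) of 5 heart muscle transcripts on each liver array, by stage and in the adult. Circles are replicate 1 and triangles replicate 2. Myl7 read 4203 and 2734 at 10.5 dpc, 127 and 1149 at 12.5 dpc, and 54.6 and 48.4 at 13.5 dpc.

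Adult liver was then compared with the mean of the 6 embryonic stages, to set the developing organ against the mature one. Genes of mature hepatocyte metabolism were higher in the adult. All 22 tested cytochrome P450 genes were higher, with a median of 5.44 log2. Cyp2c50 was at least 146-fold higher, at 3875 ± 1936 (SD, n = 2) in the adult and between -118 and -2.65 on the 12 embryonic arrays (7.19 log2, SE 0.20, adjusted p = 3.07e-10). All 12 take the floor value in the fit, while the 2 adult arrays read 2506 and 5244. The SE and adjusted p of this gene, and of others with a group at the floor, thus understate the spread between arrays. Cyp3a11, which oxidises steroids and drugs, was higher by 6.63 log2 (SE 0.18, adjusted p = 2.53e-10). Of 17 genes of bile acid synthesis and transport 15 were higher, with the bile acid importer Slc10a1 at 5.49 log2 (SE 0.50, adjusted p = 2.28e-06) and the transporter Slco1a1 at least 34.8-fold higher. Of 18 genes of the urea cycle and amino acid breakdown 17 were higher. Tyrosine aminotransferase (Tat) was at least 44.2-fold higher, at 1096 ± 3.66 in the adult, and arginase 1 (Arg1), the last enzyme of the urea cycle, was higher by 5.28 log2 (SE 0.29). Of 17 phase 2 conjugation genes 13 were higher, among them the glucuronosyltransferase Ugt2b5 at 5.76 log2 and Ugt3a2, at least 50.9-fold. Of 16 complement genes 14 were higher, including the lectin Mbl2 at 6.10 log2 and C4bp at 5.73 log2. Of 16 genes of fatty acid oxidation and ketone synthesis 10 were higher, including the peroxisomal enzymes Acaa1b at 5.86 log2 and Ehhadh at 3.42 log2. None of these 6 lists held a gene that was lower, and the counts adjusted over the list alone were the same. Some members lay at the floor on all 12 embryonic arrays, such as Cyp2c50, Slco1a1, Tat and Ugt3a2. They passed the filter only through the 2 adult arrays and could only read higher, so these counts are in part set by the filter. The largest increases by the fixed rule were the carboxylesterase Ces1c, at least 184-fold (7.52 log2, SE 0.15, adjusted p = 2.95e-11), the ketosteroid reductase Akr1c6, at least 146-fold, and the major urinary protein Mup3. For Mup3 (7.30 log2) and C4bp 11 of the 12 embryonic arrays lay at the floor, so these differences are set by it.

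Camera called each of these lists. With an estimated correlation the P450 list (adjusted p = 4.94e-17, then 0.029), the bile acid list (9.67e-11, then 0.0154) and the urea cycle list (6.19e-11, then 0.0323) held. The complement list had adjusted p = 5.45e-10 but adjusted p = 0.0979 with an estimated correlation, and the phase 2 list 6.88e-09 but adjusted p = 0.0644 with an estimated correlation. The fatty acid list had adjusted p = 5.83e-07 but adjusted p = 0.0671 with an estimated correlation. With either adult array left out, the counts of higher minus lower genes fell for P450 and bile acids, and without adult replicate 2 for phase 2. Genes above the filter on the adult arrays alone, such as Cyp2c50, Slco1a1 and Ugt3a2, then left the test, since the filter needs 2 arrays. How much of the fall this makes up was not counted. Without the 10.5 and 12.5 dpc arrays, 5 fatty acid genes were higher.

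The genes lower in the adult included those of cell division, blood formation and fetal identity. All 26 mitosis genes were lower, with a median of -4.34 log2. Mki67 was at least 94.8-fold lower, at 20.6 ± 5.07 (SD, n = 2) against 2663 ± 1181 (SD, n = 12; -6.57 log2, SE 0.11, adjusted p = 1.37e-11), and the ubiquitin-conjugating enzyme Ube2c at least 89.2-fold lower. Of 29 DNA replication genes 26 were lower and 3 not called, with the ribonucleotide reductase subunit Rrm2 at -6.38 log2 (SE 0.21) and the helicase subunit Mcm5 at -5.52 log2 (SE 0.19). Of 18 definitive red cell genes 16 were lower, including the anion exchanger Slc4a1 at -6.03 log2 (SE 0.19, adjusted p = 7.61e-10) and Ermap at -5.91 log2 (SE 0.11, adjusted p = 2.62e-11). Of 12 hepatoblast and oncofetal genes 8 were lower and 1 higher. Afp was at least 236-fold lower, at 10.5 ± 4.13 against 5893 ± 619 (-7.88 log2, SE 0.08, adjusted p = 1.27e-12), although 1 of its 4 other tested probe sets read 1.36 log2. The imprinted gene Dlk1, a hepatoblast surface protein, was lower, at -6.62 log2 (SE 0.15). The higher member was the peptidase Dpp4, at 2.27 log2, named after its value was seen. Of 16 blood stem and progenitor cell genes 8 were lower, including Lmo2 at -4.91 log2 and Myb, at least 20.6-fold, and 2 were higher, Erg at 3.30 and Hlf at 1.01 log2, named after their values were seen. The largest decreases by the fixed rule also held the embryonic globin Hbb-y, at least 136-fold, and Cd24a at -6.95 log2 (SE 0.09). For Ermap and Rrm2, 1 of the 2 adult arrays lay at the floor.

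Of 19 genes of insulin and insulin-like growth factor signalling 5 were higher and 5 lower. The fetal growth factor Igf2 was lower, at -4.76 log2 (SE 0.13, adjusted p = 1.9e-10), at 176 ± 43.2 (SD, n = 2) against 4721 ± 504 (SD, n = 12). Igf1, the growth factor that liver releases under growth hormone, was higher by 3.35 log2 (SE 0.24, adjusted p = 3.75e-07). The other higher members were Igfals, Socs2, Igfbp2 and the growth hormone receptor Ghr, between 2.04 and 3.00 log2. The other lower members were Igfbp5, Igf2r, Igfbp1 and Igf1r, between -2.62 and -1.68 log2. These 8 were named after their values were seen. Higher minus lower, the count was 2 without adult replicate 1 and -1 without its replicate 2. The counts of this list and of the 5 lists before it were the same when adjusted over the list alone. Camera called neither this list (adjusted p = 0.573) nor the stem cell list (adjusted p = 0.398). The mitosis list was called both ways (adjusted p = 7.53e-15, then adjusted p = 0.021 with an estimated correlation). The replication list had adjusted p = 9.84e-11 but adjusted p = 0.0849 with an estimated correlation, and the red cell list 7.6e-08 but adjusted p = 0.109 with an estimated correlation. The oncofetal list had adjusted p = 0.00241 but adjusted p = 0.0859 with an estimated correlation.

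In all, 1675 genes were higher and 3345 lower in adult liver, with a median over all tested genes of -0.21 log2 as deposited and -0.05 log2 after quantile normalization. After quantile normalization 2304 were higher and 3081 lower. As deposited, the 99th percentile of intensity was 1319 and 2249 on the adult arrays and 2448 to 2881 on the embryonic liver arrays. Adult liver differed from the stages in turn at 5258, 5332, 5289, 5139, 5010 and 4681 genes, from 10.5 to 16.5 dpc. Camera called 15 lists higher and 10 lower, of which 6 held with an estimated correlation.

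**Figure D4:**
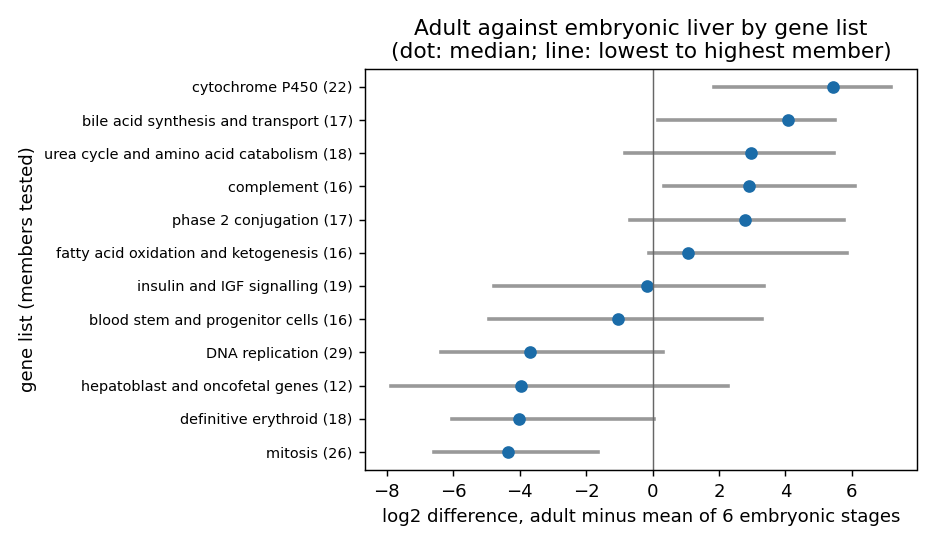
Log2 difference between adult liver and the mean of the 6 embryonic stages (horizontal axis) for the 12 gene lists assigned to this comparison (vertical axis, with the number of members tested). Dots are medians and lines run from the lowest to the highest member. The P450 list has the highest median, 5.44 log2, and the mitosis list the lowest, -4.34 log2.

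Embryonic liver was compared with the rest of the embryo at the 4 matched stages, to separate liver genes from those of other embryonic tissue. The 2 tissues lay in the 2 sets of arrays that differ in form, so tissue and array set cannot be told apart in any value of this comparison. The hybridisation control transcripts read lower on the liver arrays for all 9 probe sets, by a median of -1.80 log2. As deposited, 2078 genes were higher and 7622 lower in liver, or 78.6% lower, with a median over all 14896 genes of -1.04 log2. Quantile normalization gave 2818 higher and 2869 lower, or 50.4% lower, and a median of -0.13 log2. Median centring gave 2905 and 4153, and scaling to the hybridisation controls 6202 higher and 819 lower, or 11.7% lower, with a median of 0.74 log2. Under all 4 scalings, 2077 genes were higher and 819 lower. Median centring and control scaling, however, each add the same amount to the liver difference of all genes. For the higher genes the agreement is thus tested by quantile normalization alone, and 819 is the lower count under control scaling.

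The genes higher in liver included hepatocyte and blood genes. Of 21 plasma protein genes 14 were higher and none lower, with a median of 2.79 log2, and 17 to 21 were higher under the other scalings. The fibrinogen beta chain (Fgb) was higher by 5.40 log2 (SE 0.31, adjusted p = 5.11e-08), at 1312 ± 809 (SD, n = 8) in liver and 18.7 ± 9.46 (SD, n = 4) in the rest of the embryo. Serpina6, the corticosteroid carrier of plasma, was higher by 5.23 log2 (SE 0.44). Of 17 coagulation genes 15 were higher, including the fibrinogen alpha chain (Fga) at 5.41 log2 (SE 0.26), and 1 was lower, protein S (Pros1) at -1.33 log2. Of 16 liver transcription factors 7 were higher, including Creb3l3, at least 39.2-fold, and Hnf4a at 3.47 log2 (SE 0.23), and 1 was lower, Tbx3 at -2.19 log2. Of 18 definitive red cell genes 12 were higher, including the ammonium channel protein Rhag at 3.48 log2 (SE 0.63) and the transcription factor Klf1 at 3.28 log2 (SE 0.46), and 2 were lower, Hba-a2 at -2.27 and Add2 at -1.02 log2. Of 11 heme synthesis genes 6 were higher, or 5 adjusted over the list alone, including Cpox at 3.89 log2 and the transporter Abcb6 at 1.73 log2. Of 22 macrophage and Kupffer cell genes 8 were higher, including Csf1r at 2.27 log2 and Fcgr1 at 2.04 log2, whose other probe set read -0.78 log2. As means over their probe sets neither was called, with Csf1r at 0.87 and Fcgr1 at 0.63 log2. The lower ones were Aif1 at -1.31 and Clec4f at -1.25 log2. The lower members of these lists were named after their values were seen, and none of them was called lower when scaled to the hybridisation controls. The counts adjusted over the list alone were the same for the other 5 lists.

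Camera called all 6 lists, and none held with an estimated correlation. The plasma protein list had adjusted p = 1.61e-09, then adjusted p = 0.211 with an estimated correlation, and the coagulation list 1.14e-08, then adjusted p = 0.447 with an estimated correlation. The transcription factor list had 0.000464, then adjusted p = 0.108 with an estimated correlation. The red cell list had 1.64e-05, then adjusted p = 0.515 with an estimated correlation. The heme list had 0.000215, then adjusted p = 0.515 with an estimated correlation, and the macrophage list 1.5e-05, then adjusted p = 0.447 with an estimated correlation. The heme count, higher minus lower, was 3 when either liver array of 12.5 or of 14.5 dpc, or the rest-of-embryo array of 12.5 or of 14.5 dpc, was left out. The macrophage count, higher minus lower, was 10 without the rest-of-embryo array of 10.5 dpc, against 8 higher and 2 lower with it.

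The largest increases by the fixed rule were genes outside the lists. Zfp622 was at least 150-fold higher (7.23 log2, SE 0.14, adjusted p = 2.82e-10), at 3811 ± 950 (SD, n = 8) in embryonic liver, 3260 in adult liver and 12.1 ± 5.73 (SD, n = 4) in the rest of the embryo. Of its 3 other tested probe sets 2 read the other way, the farthest at -3.05 log2, and the mean over its probe sets was 0.85 log2 and not called. Slc12a8 was at least 143-fold higher (7.16 log2, SE 0.15), with 3321 in adult liver. The bicarbonate transporter Slc4a8 was 128-fold higher, with 5666 in adult liver and 1 of 2 other probe sets at -0.96 log2.

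Many genes of tissues outside the liver read lower in liver, although camera called none of these lists against the all-gene shift. The filter sets these counts in part. A gene at the floor on all 8 liver arrays passed it only through the rest-of-embryo arrays and could only read lower. In the same way, a gene at the floor on all 4 rest-of-embryo arrays could only read higher in liver. Of the skeletal muscle list, 18 genes were tested here and 11 in the liver fit. Of 22 neural genes 16 were lower and 1 higher. The fatty acid binding protein of radial glia Fabp7 was lower, at -6.80 log2 (SE 0.15, adjusted p = 3.59e-10), with a mean of 57.9 (n = 8) against 6246 ± 741 (SD, n = 4), and the neuronal stathmin Stmn2 at -6.07 log2 (SE 0.18). The transcription factor Zic1 and the reticulon Rtn1 were lower, at -6.98 and -6.86 log2, the latter at least 116-fold. Of 18 skeletal muscle genes 16 were lower, including the embryonic myosin Myh3 at -5.46 log2 (SE 0.35) and Mylpf at -4.33 log2 (SE 0.23). Of 27 extracellular matrix genes 25 were lower, including the laminin chains Lama4 at -3.63 and Lamb1 at -3.25 log2, and 2 were higher, Lamc1 at 3.11 and Eln at 1.10 log2. Of 18 cartilage and bone genes 13 were lower, including the cartilage protein Cnmd at -5.12 log2 and Sox9 at -4.99 log2, with 1 of 2 other Sox9 probe sets at 0.67 log2. Of 23 Hox genes 16 were lower, including Hoxc8 at -4.36 log2, and 3 were higher, with Hoxd13 at 3.53 log2 but its other probe set at -2.42 log2 and their mean at 0.56 log2 and not called. Of 11 epidermis genes 5 were lower, including the keratins Krt1 at -3.65 log2 (SE 0.56) and Krt5 at -3.26 log2 (SE 0.45), and 3 were higher, Trp63, at least 9.24-fold, Lor at 2.10 and Krt17 at 2.02 log2. The other lower ones were Krt15 at -3.14, Krt10 at -3.03 and Dsp at -1.19 log2. Also higher against their lists were Pou3f2 of the neural list, at least 26.8-fold, Col9a2 of the cartilage list at 2.81 log2, and Hoxc5 and Hoxb3 at 1.88 and 1.26 log2. Members of the last 3 sentences other than Krt1, Krt5 and Hoxd13, with Lamc1 and Eln, were named after their values were seen.

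Of the lower group, some arrays lay at the floor for several of the genes named in this comparison: 3 of 4 for Fgb, Fga and Krt17, 7 of 8 for Zic1 and Cnmd, 6 of 8 for Krt1, and 5 of 8 for Myh3, Lama4 and Hba-a2. The counts of these 6 lists were the same when adjusted over the list alone. Camera gave adjusted p = 0.138 for the neural list, 0.229 for muscle, 0.24 for matrix, 0.6 for cartilage and bone, 0.618 for Hox and 0.209 for epidermis. Scaled to the hybridisation controls, 13 neural, 8 muscle, 4 matrix, 7 cartilage and 9 Hox genes were lower. In that scaling the epidermis list turned, with 5 higher and 3 lower, and without the rest-of-embryo array of 14.5 dpc its counts were equal. At single stages, 9913, 9027, 9544 and 9948 genes differed as deposited, from 10.5 to 14.5 dpc. These 4 counts treat the single rest-of-embryo array as varying like the liver arrays. Camera called 16 lists higher and 2 lower in liver, and 0 held with an estimated correlation.

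The last comparison asked whether the difference between liver and the rest of the embryo changed from 10.5 to 14.5 dpc. The difference in slope, liver minus rest of the embryo, rose for 14 of 18 definitive red cell genes, 19 of 26 mitosis genes and 19 of 29 DNA replication genes. It rose for 14 of 17 coagulation genes and fell for 1. It fell for 20 of 27 extracellular matrix genes, 10 of 18 skeletal muscle genes and 8 of 11 epidermis genes. No set test was run on the slopes. As deposited, the slope rose for 893 genes and fell for 1506, or 62.8% falling, by limma with an adjusted p under 0.05 and at least 0.25 log2 per day. Median centring gave 1252 and 1156, or 48.0% falling. Single rest-of-embryo arrays decided much of these counts. Without that of 14.5 dpc, 474 rose and 318 fell, and without that of 10.5 dpc 413 rose and 987 fell. Without liver replicate 2 of 14.5 dpc, 570 rose.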

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

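The tests of processing, of tissue and of the residual SD of the splits below were chosen after the result was seen, and the comparison with other splits of the arrays before.

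The change with stage of the difference between liver and the rest of the embryo was singled out because the interaction of tissue with stage tests a difference between tissues directly. The slope rose for 893 genes and fell for 1506. The steepest rises were Pzp, a plasma protease inhibitor (1.43 log2 per day, SE 0.12, limma adjusted p = 0.000394), the apolipoprotein Apoc4 (1.31, SE 0.17, adjusted p = 0.00151) and the red cell antigen Kel (1.30, SE 0.22, adjusted p = 0.00453). Pzp read -36.3 and 15.0 on the liver arrays of 10.5 dpc and 1249 and 1238 on those of 14.5 dpc, against 24.8 at most in the rest of the embryo, so that the floor sets part of its slope. The steepest falls were the mast cell protease Cpa3 (-2.07, SE 0.19, adjusted p = 0.000467), the fast skeletal troponin Tnnt3 (-1.70, SE 0.15, adjusted p = 0.000394) and the matrix protein Dpt (-1.54, SE 0.23, adjusted p = 0.00282). In the rest of the embryo, from 10.5 to 14.5 dpc, Cpa3 went from 21.9 to 1903, Tnnt3 from 32.8 to 3653 and Dpt from 36.0 to 2710. The floor enters other slopes than that of Pzp as well. Of the 8 liver arrays 4 lay at the floor for Apoc4 and 3 for Tnnt3, as did 1 of 4 rest-of-embryo arrays for Cpa3. Without the rest-of-embryo array of 14.5 dpc, Dpt was no longer called at -0.52 log2 per day, nor Apoc4 at 1.04. Without that of 10.5 dpc Kel was no longer called at 0.91, nor at 1.03 without the 10.5 and 12.5 dpc arrays, and Pzp was no longer called at 1.20 with no floor.

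Of the 81 within-stage splits of the 12 arrays into 8 and 4, only the real split (1 of 81) called as many genes by slope, 2399 against 25 in the highest other split. Each other split puts rest-of-embryo arrays among the liver arrays, which raised the median residual SD of the slope fit from 0.22 to at least 0.58 log2, so the count says nothing on whether chance made the slopes. Single arrays moved them: 474 rose and 318 fell without the rest-of-embryo array of 14.5 dpc, 413 and 987 without that of 10.5 dpc, and 570 rose without liver replicate 2 of 14.5 dpc. For the overall difference it was also 1 of 81, with 9700 genes against 0 in the highest other. The other splits mix the 2 sets of arrays here too, and with 81 splits the share cannot lie under 1 of 81. The count therefore only reflects that the 2 sets differ, as their forms of values already show. It does not separate tissue from array set.

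The excess of lower calls in liver, 7622 against 2078, was weighed as an effect of scale or of tissue. All 9 control probe sets, whose transcripts are added at hybridisation, read lower on the liver arrays, between -2.27 and -1.49 log2 with a median of -1.80, which is consistent with a different scale of the 2 sets of arrays. Scaled to these controls, 11.7% of called genes were lower in liver, but this follows from shifting all genes by that offset and adds no evidence. Whether tissue adds to the excess cannot be told apart from the array set, because each tissue lies in 1 set.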

How the results depend on the processing

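Scaling to the hybridisation controls, leaving out probe sets below 0 on any liver array and leaving out the 10.5 and 12.5 dpc arrays were chosen after seeing the data. Where a result changed below, the cause was not tested unless fewer genes, fewer arrays or a different threshold make it plain. Of named genes, 1506 values under alternatives other than single left-out arrays kept direction and call, 11 lost the call and 3 reversed. With single arrays left out, 1193 were kept and 3 lost the call. Counts of gene lists stayed within 1.5 times in 588 cases, moved further in 39 and reversed in 2 under the former, and stayed in 478 and moved in 16 with single arrays left out.

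Quantile normalization gave 2869 genes lower in liver than in the rest of the embryo, and 4692, 5381 and 6092 at 10.5, 11.5 and 12.5 dpc alone. Median centring gave 4153 lower. Scaling to the controls gave 6202 higher and 819 lower, 6277 at 10.5 dpc alone, 467 rising slopes, 224 genes from 11.5 to 12.5 dpc, and a reversed epidermis count of 2 (higher minus lower). The filter at the 75th percentile, which tests fewer genes, gave 581 lower at 16.5 than 10.5 dpc, 1056 higher in the adult and 1279 higher in liver than in the rest of the embryo. Of the steps after 12.5 dpc, that to 13.5 dpc went from 12 calls to 20 with quantile normalization, 0 with median centring, 1 with no filter, 1 with no floor, 6 with the floor at the 40th percentile, 0 with all 18 arrays in one fit, 0 at adjusted p under 0.01 and 0 without probe sets below 0. That from 13.5 to 14.5 dpc went from 8 to 4 with no floor, 5 with the floor at the 40th percentile, 13 with the mean of probe sets, 2 at adjusted p under 0.01 and 4 without probe sets below 0. That from 14.5 to 16.5 dpc went from 5 to 3 with the filter at the 75th percentile, 10 with no floor, 3 at adjusted p under 0.01, 17 with control scaling and 2 without probe sets below 0. With no minimum change the counts were 2904 higher and 2138 lower for 16.5 against 10.5 dpc, 3349 and 6020 for the adult, 4228 for any stage, and 1946 and 754 for the first 2 steps. For the adult against each stage they were then 8377, 8516, 8469, 8368, 8220 and 7714. An adjusted p under 0.01 left 377 rising and 704 falling slopes. With an estimated correlation 1, 6 and 0 lists were called, against 29, 25 and 18. Without the 10.5 and 12.5 dpc arrays, 913 genes rose and 308 fell, 1278 changed at any stage, 472 slopes rose and 700 fell, Ppbp read -0.45 log2 and the platelet list -3 (higher minus lower). Without _x_at and _s_at probe sets, Hbb-b2 read -1.83 and Uroc1 -0.85 log2.

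With each array left out in turn, calls from 10.5 to 11.5 dpc ranged from 557 to 1723, to 13.5 dpc from 0 to 52, to 14.5 dpc from 1 to 10, to 16.5 dpc from 3 to 8, rising slopes from 413 to 925 and falling slopes from 318 to 1566. A group left with 1 array is assumed to vary like the others. With the replicate block the step to 13.5 dpc gave 0 calls and that to 14.5 dpc 5. No named gene lost its call or reversed, and no other count of a whole comparison moved by over 1.5 times. Over the 21 pairs of liver groups, the difference between replicates correlated between -0.354 and 0.254 across genes, over 0.1 in 5 pairs, so the numbers do not pair the samples. Probe sets near or below 0 limit all values near the floor.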

Other observations

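All tests of an explanation in this part were chosen after the result was seen.

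Several groups not described above moved during liver development. Adjusted over the list alone the counts were the same as over all genes. From 10.5 to 16.5 dpc 18 of 19 coagulation factor genes rose (camera adjusted p = 7.17e-13, but adjusted p = 0.119 with an estimated correlation), as did all 11 heme synthesis genes (6.59e-10, but adjusted p = 0.0991 with an estimated correlation). Of 16 complement genes 11 rose (3.01e-07, but adjusted p = 0.122 with an estimated correlation). Of 19 endothelial genes 3 rose, the liver sinusoid receptors Stab2 and Lyve1 at 2.00 and 1.07 log2 and Eng at 1.37 log2, and 2 fell, Tek at -1.65 and Emcn at -2.64 log2, named after their values were seen. Camera did not call that list (adjusted p = 0.138). None of 21 ribosomal protein genes and none of 27 genes of oxidative phosphorylation was called by limma.

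In adult against embryonic liver, 10 of 18 liver transcription factors were higher, and camera called them also with an estimated correlation (adjusted p = 6.65e-06, then 0.0338). Of 18 acute phase genes 14 were higher and 2 lower, the metallothioneins Mt1 and Mt2, both at -1.48 log2 and named after their values were seen (adjusted p = 4.26e-09, but adjusted p = 0.0879 with an estimated correlation). Of 21 ribosomal protein genes 20 were lower as deposited, with a median of -1.61 log2, but 9 after quantile normalization (adjusted p = 1.51e-05, but adjusted p = 0.481 with an estimated correlation). These counts too were the same when adjusted over the list alone. Golt1a read 325 ± 5.49 at 13.5 dpc, -26.1 ± 25.8 at 14.5 dpc and 273 ± 8.74 at 16.5 dpc (SD, n = 2 each).

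Heart muscle transcripts were high on both liver arrays of 10.5 dpc and raised on both of 12.5 dpc, with list medians of 900 and 472, and of 126 and 355, against 44.6 to 57.3 on the arrays of 11.5 and 13.5 dpc. RNA degradation is argued against for replicate 2 of 10.5 dpc and both arrays of 12.5 dpc, whose Gapdh 3' to 5' ratios reach at most 0.862, within the 0.744 to 0.886 of the liver arrays of 11.5 dpc and of 13.5 dpc onward. Replicate 1 of 10.5 dpc had the highest heart median, 900, and a ratio of 2.82. Replicate 2 of that stage read 472 at a ratio of 0.803, which argues against degradation for the high level that both arrays share. For the excess of replicate 1 over replicate 2 degradation stays open, since a high ratio alone does not show that it raised heart readings. Heart gene activity set by the labelled stage alone is argued against for the gap between the 2 arrays of 12.5 dpc. There 15 of 16 genes read higher on replicate 2, by a median of 1.66 log2, against an SD of 0.35 log2 over all genes. For the rise shared by both arrays stage stays open. Of the list 87.5%, 14 of 16 genes, read higher on both arrays of 12.5 dpc than on all 4 of 11.5 and 13.5 dpc. Heart tissue taken along with the liver may also explain the values and was not decided by any test here: 93.75% of the list lay higher on replicate 2 than on replicate 1 of 12.5 dpc, by a median of 1.66 log2, but this restates the pattern.

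Sex-linked transcripts differed between pools of embryonic liver. Eif2s3y read 1.78 on replicate 2 of 11.5 dpc and -3.41 on replicate 1 of 12.5 dpc, but 169 on replicate 2 of 12.5 dpc, where Xist read 234 against 1272 on replicate 1. Over the 12 arrays Xist fell as the mean of the Y-linked genes rose (Pearson r = -0.845, permutation p = 0.00028, adjusted p = 0.000373; Spearman rho = -0.90, permutation p = 0.00026, adjusted p = 0.00052; 4 relations tested), with r = -0.756 without the 2 arrays farthest from the median and the 2 arrays opposite in 5 of 6 stages. Noise near the floor is argued against, as the lowest pairwise r of the 3 Y-linked genes was 0.845. For that pair, Eif2s3y and Uty, Spearman rho was 0.66. Its r was 0.589 without the 2 arrays farthest from the median, so these arrays carry part of the relation. Pools with different shares of male embryos may explain the differences in sex-linked transcripts. Labelled stage does not account for differences between the 2 arrays of 1 stage, as at 12.5 dpc. For differences between stages it was not separated from the pools and stays open. In the rest of the embryo, from 10.5 to 14.5 dpc, Eif2s3y read 56.5, 308, 295 and 9.70, and Xist 2697, 997, 1498 and 3872. The liver arrays of 14.5 dpc read 113 and 129 for Eif2s3y. Liver and rest-of-embryo samples of 1 stage thus differed in these transcripts too.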
